A study of Mus musculus with 12 samples.

How the data were processed

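Gene expression was measured on Illumina bead arrays in brain gliomas of 12 mice, 6 with intact Tlx and 6 in which Tlx had been deleted. Tlx is the older name of the nuclear receptor gene Nr2e1, which is known for its role in neural stem cells. Per the labels, tumours arose in mice that carried a floxed Tlx allele on both chromosomes, a tamoxifen-activated Cre under the Nestin promoter and a Nestin-driven Tva, the receptor through which an avian retrovirus can enter cells. Tamoxifen was given from 2.5 weeks after the tumours were started. Littermates with Cre form the knockout group and littermates without Cre the intact group, so the groups differ in carriage of the Cre transgene as well as in Tlx. Per the labels' protocols, tissue was taken once neurological symptoms were severe, stood 4 h in RNAlater and was extracted with Trizol followed by a column clean-up with DNase, and biotinylated cRNA was hybridised. Each array is a separate animal. The labels give no replicate number shared between the groups, so replicates were numbered within each group in the order of deposition and the numbers pair no animals.

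The authors deposited 2 tables of the whole series. Per the file headers, the first holds a signal intensity and a detection p-value for each of 45135 probes on each array, on a linear scale and without normalization between arrays. The second is the authors' value table of 45134 probes, also intensities on a linear scale, and how these were normalized is not given in the sources used here. Each array of the value table had a rank correlation of at least 0.99995 with the same animal's unnormalized array, and its column medians of 145 to 150.2 lay close together, against 134.5 to 161 in the unnormalized table. The value table served as an alternative only. Its values are not centred, and a single-colour intensity carries no direction. The number of columns belonging to other samples was 0. How the deposited detection p-values were computed is not given in the sources used here. They were not plain ranks among negative-control probes, but the background that they imply, with means of 124 to 146 and SDs of 5.74 to 6.83 intensity units per array, lay just below the median signal.

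Probe names came from the platform annotation supplied with the series, with symbols updated through Entrez identifiers against the mouse reference table of assembly GRCm38.p6. Of the 45135 probes, 34772 had 1 gene symbol, 18 had several and 10345 were not named there. Of the 34772, 34694 had an Entrez identifier in the reference table. No genome build is named for the array, so no coordinates are given, and the reference served only for names, chromosomes and the order of neighbouring genes.

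Signals were background-corrected and normalized with neqc in limma 3.58.1 under R 4.3.3, which fits a normal-exponential model from the detection p-values, adds an offset of 16, applies quantile normalization and takes log2. A probe was kept if its detection p was below 0.05 on at least 3 of the 12 arrays, which left 28002 probes, 23118 of them with 1 gene. A gene with several such probes was represented by the probe with the highest mean log2 intensity over all arrays. This concerned 5779 of the 14155 genes tested. Knockout and intact arrays were compared by limma (lmFit and eBayes, two-sided) with Benjamini-Hochberg adjustment over all 14155 genes at an adjusted p threshold of 0.05. Differences are log2 knockout minus intact. Where a probe was detected on no array of a group, the difference has only a bound. It is written as "at least N-fold" and compares the bright group's mean with the dim group's mean of, per array, the higher of the probe's own value and the lowest value of any detected probe.

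A total of 28 gene lists, of signalling themes, cell types and quality measures, was fixed before the data were examined, and 334 of their 414 distinct genes were measured. Lists were tested with camera, a competitive test of a list against all other genes, at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 28 lists. Camera with the correlation estimated from the data, fry (a rotation test of whether a list's genes move on balance in 1 direction) and camera on ranks were run beside it. A list mean is the average over a list's genes of each gene's log2 deviation from its mean over the 12 arrays. It was compared between groups with its standard error and an exact two-sided permutation test. The rule for named genes was also fixed beforehand: Nr2e1, 12 genes in each direction (those past the threshold by size of difference, then those of smallest unadjusted p, leaving out clone and predicted-gene names), and up to 4 members of each list by smallest p, with every measured member of the published Tlx targets and the sex-chromosome markers. Not every gene taken by this rule is reported here. Ages were compared by an exact two-sided permutation test.

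Depth was similar on all arrays. Between 50.8% and 54.8% of probes had a detection p below 0.05, and the number of arrays, 6 per group, limits the precision. Over the genes tested, Pearson r was 0.936 to 0.982 between arrays of 1 group and 0.906 to 0.982 between groups. The median SD of a gene between arrays of a group was 0.35 on the log2 scale. The fit was tested on simulated data in which 200 of the 14155 genes were changed in 6 of 12 arrays: 66% of 50 genes changed by log2 1 were recovered, 94% at 1.5, 94% at 2 and 98% at 3, and 6.88% of the calls were false. In the simulated data the 1 shifted list was found and 1 other list was called. Simulated values were drawn independently for each gene and array, with no blocks and no correlation between genes. These rates therefore need not hold for the real arrays.

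The files record no slide or scan, so a slide block could not be fitted. Among 9153 probes that were detected on no array, the arrays of the first 6 columns of the deposited table deviated together, and so did those of the last 6. The median r was 0.40 within the first 6 columns, 0.28 within the last 6 and 0.16 between them, and of the 462 ways to divide the 12 arrays equally this division had the highest contrast. The first 6 columns hold 5 knockout arrays and intact replicate 3, and the last 6 hold 5 intact arrays and knockout replicate 1. This column block was added to the fit as an alternative. A block of a second kind came from the labels, whose titles end in a number or code for each animal. Intact replicates 1 and 2 and knockout replicates 2, 5 and 6 carry numbers of 1 closely spaced run (series A), intact replicate 3 a number of another run (series B), knockout replicates 1, 3 and 4 numbers of a further run (series C), and intact replicates 4, 5 and 6 codes of other formats (series D). What the numbers stand for is not given in the labels. Series A alone holds both groups, and in it the column block coincides with the group, so both blocks could not be fitted together. Both blocks were chosen after the data were seen.

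On 5 arrays, knockout replicates 2 to 5 and intact replicate 3, all in the first 6 columns, the probe of Pdia3 read 60.8 to 73.1 intensity units, far below the array background, against 2373 to 5877 on the other 7 arrays. Such readings, more than 6 SD below background, occurred for 66 probes, 93 times on arrays of the first 6 columns and 5 times on the others. Of these probes 7 had a log2 intensity of at least 7 on another array. They were kept, because the detection filter does not remove them, and the 5 arrays were left out in an added alternative.

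The other alternatives, all fixed beforehand, were no background correction, cyclic loess or median scaling in place of quantile normalization, a filter at 6 arrays or none, the authors' value table, the mean of a gene's probes, array weights, a variance trend with robust moderation, age as a covariate, tests of single probes, and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.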

Results

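The series holds 12 bead arrays of mouse brain glioma, 1 per animal, with 6 Tlx-intact and 6 Tlx-knockout tumours. Median signal was 134.5 to 161 intensity units per array, and 50.8% to 54.8% of the 45135 probes were detected, so no array stood apart in depth. The design asks how loss of Tlx, a nuclear receptor of neural stem cells, changes gene expression in established gliomas. It implies 1 comparison, knockout against intact, with the age at which animals fell ill as a second readout.

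Knockout animals were older than intact animals when their tumours were collected. Mean age was 62.2 ± 10.1 days (SD, n = 6) in the knockout group and 44.8 ± 5.08 days (SD, n = 6) in the intact group. The difference of 17.3 days (SE 4.63) had an exact two-sided permutation p of 0.00649, and 5 of 6 knockout animals were older than every intact animal. Since animals were taken when symptoms were severe, age at collection also differs between the groups in every gene comparison below.

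Nr2e1, the targeted gene, had a lower mean in knockout tumours, but the difference did not pass the threshold. Its probe (ILMN_2689177) read 6.14 ± 0.44 log2 units in intact and 5.55 ± 0.54 in knockout tumours (SD, n = 6 each), a difference of -0.58 (SE 0.26, limma adjusted p = 0.405). Knockout tumours thus averaged 66.8% of the intact normalized intensity, a share that the added offset of 16 draws upward. Raw signals of the probe, 139 to 216 intensity units, lay near the background means of 124 to 146 per array. The probe was detected on all 12 arrays, and the single values overlapped, with knockout replicate 4 at 6.21 and intact replicate 6 at 5.37. With the column block in the fit the difference was -0.93 (SE 0.33, adjusted p = 0.541), and with the label series it was -0.71 (SE 0.42, adjusted p = 0.999). Where the probe lies relative to the deleted part of the gene is not given in the sources used here. The tissue also holds cells in which Cre is not active. The level of this probe was planned as a check of the labels, but for these reasons it does not check them.

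Lyzl4 and Adgrf5 were the genes past the threshold. Lyzl4 encodes a lysozyme-like protein. Its probe (ILMN_1232761) was detected on 6 of 6 intact arrays at 7.37 ± 0.40 log2 units (SD, n = 6) and on 0 of 6 knockout arrays, at least 6.79-fold lower in knockout tumours (fitted log2 -2.88, SE 0.18, adjusted p = 4.34e-06). Adgrf5, an adhesion G-protein-coupled receptor of lung epithelium and endothelium, read 6.28 ± 0.30 in knockout and 4.68 ± 0.46 in intact tumours (SD, n = 6 each), 3.03-fold higher (log2 1.60, SE 0.22, adjusted p = 0.0252). It was detected on 6 of 6 knockout and 2 of 6 intact arrays, so its fold is set in part by the floor, and its second probe differed by 0.26.

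By limma, 1 of 14155 genes was higher and 1 lower in knockout tumours after adjustment, and 1690 genes (11.9%) had an unadjusted p below 0.05, 881 of them higher and 809 lower, where 708 would be expected by chance. The fitted difference of Lyzl4, against knockout arrays that did not detect it, was -2.69 with the column block (adjusted p = 0.000719) and -2.89 with the label series (adjusted p = 0.0145). Adgrf5 lost its call in both, at 1.76 (adjusted p = 0.314) and 1.02 (adjusted p = 0.999), and its adjusted p ran from 0.00612 to 0.999 over all alternatives, leaving out 1 array included, against 1.67e-06 to 0.525 for Lyzl4. Without background correction the differences shrank to -0.98 for Lyzl4, still called, and 0.44 for Adgrf5, no longer called. Leaving out 1 array moved the count of higher genes to 0 for each of intact replicates 3 to 6 and knockout replicates 2, 4, 5 and 6, to 2 for knockout replicates 1 and 3, to 4 for intact replicate 2 and to 88 for intact replicate 1. The count of lower genes became 15 without intact replicate 1 and 3 without knockout replicate 1.

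**Figure D1:**
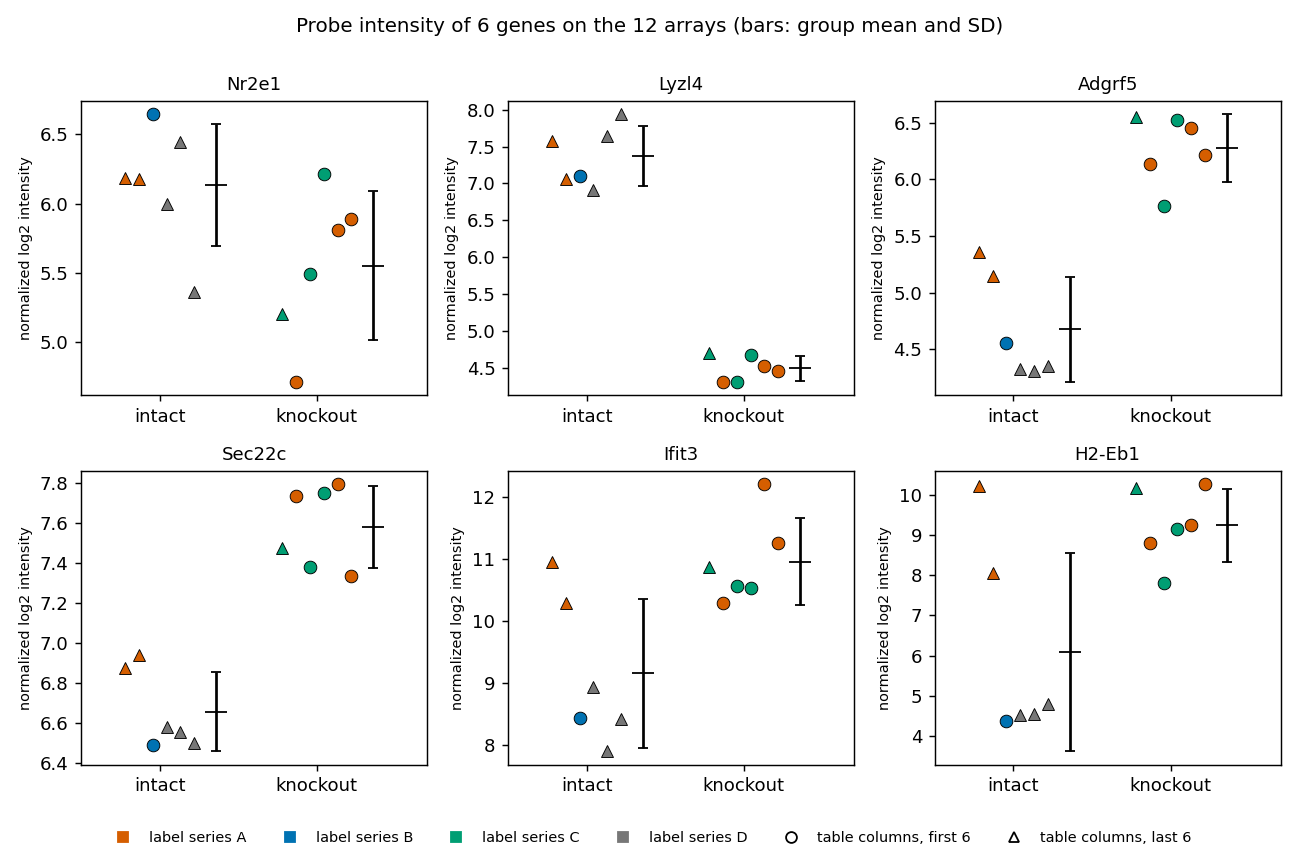
Normalized log2 intensity (vertical axis) of 6 genes in intact and knockout tumours, 1 point per array, with the mean and SD of each group as a bar at its right. Colours mark the label series and symbols the column block; Lyzl4 is at 6.91 or higher on every intact array and at 4.70 or lower on every knockout array, while Ifit3 and H2-Eb1 on the 2 intact arrays of series A lie among the knockout arrays.

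Other named genes did not pass the adjusted threshold and are given as values. Sec22c, of transport between endoplasmic reticulum and Golgi, came closest, with a difference of 0.92 (SE 0.14, adjusted p = 0.0639) and every knockout array above every intact array. Its other probes had smaller differences, 0.31 and 0.46, and it lies 2 measured genes from Lyzl4 on chromosome 9. The growth factor gene Gdnf was at 1.24 and the E3 ligase gene Trim62 at 1.92, both with adjusted p = 0.184. Samd9l, which is known to be induced by interferon, as is Parp10, was at 1.51. Slc22a30, the transcription factor gene Myb and Parp10 were detected on 0 of 6 intact arrays, and were at least 1.24-fold, 1.33-fold and 1.49-fold higher in knockout tumours. The differences of Myb, Adap1 (0.84), Spring1 (1.15) and Arl14epl (1.87) were not shared by their other probes, which had the opposite sign. With the label series in the fit Trim62 was at 0.74, Gdnf at 0.53, Spring1 at 0.38 and Arl14epl at 0.45. Sec22c was then at 0.71, Samd9l at 1.05 and Adap1 at 0.66. The fitted differences of Slc22a30, Myb and Parp10 did not shrink. None of these genes was called in that fit (limma adjusted p = 0.999 for each).

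On the lower side, Erdr1 had the widest difference at -3.46 (SE 0.66, adjusted p = 0.184), with 11.6 ± 0.92 in intact and 8.13 ± 1.65 in knockout tumours (SD, n = 6 each), and its second probe was at -3.13. Dnajc1 (-0.95), the neuronal calcium-binding gene Necab1, Psmc3ip (-1.24), the blood-brain barrier transporter Slco1c1 (-0.75), Nhlrc1 (-0.72), Sorbs2 (-0.85), Terb1 (-0.68), the matrix link protein Hapln1 and the claudin Cldn10 (-1.43) had adjusted p between 0.184 and 0.196. The other probe of Sorbs2 was at -0.19, and those of Cldn10 were at -0.25 and -1.13. With the label series in the fit Psmc3ip was at -0.58, Dnajc1 at -0.72, Slco1c1 at -0.50, Nhlrc1 at -0.43 and Cldn10 at -1.22. Sorbs2 (-1.11) and Terb1 (-0.85) were wider there, and none of these was called. Necab1 and Hapln1 were detected on 0 of 6 knockout arrays, at least 1.71-fold and 1.22-fold lower there. Gnat1 was at -2.33 (adjusted p = 0.185), but on knockout replicates 2 to 5 its probe read 4.07 to 4.11, as low as the Pdia3 probe on the arrays where that one failed. In all, 92 genes had fully separated groups (0.650%), where chance gives 0.216% on average over all divisions of the arrays. Genes vary together, so a single division can lie well off that average, and other divisions were not counted. The groups also largely coincide with the column block and differ in age, so the excess cannot be assigned to Tlx.

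Interferon-response genes were higher in knockout tumours as a list. All 18 measured members had a difference above 0, with a median of 0.92, and camera gave an adjusted p of 9.28e-08. Ifit3 (1.79), Irf7 (1.08), Isg15 (1.52) and Usp18 (1.48), which belong to the antiviral response, passed when adjusted over the list alone, as 4 of 18 did, and 0 of 18 passed over all genes tested. The call was lost when the correlation between genes was estimated (adjusted p = 0.807 with an estimated correlation). The list mean differed by 0.88 (SE 0.39, exact two-sided permutation p = 0.0606, n = 6 each). With the column block it differed by 1.08 (SE 0.54), by 1.22 within the first 6 columns and by 0.95 within the last 6, each of which sets 5 arrays of 1 group against 1 of the other.

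Antigen-presentation genes were higher as a list too. All 16 measured members were above 0, with a median of 0.51 (camera adjusted p = 7.38e-05, and adjusted p = 0.807 with an estimated correlation). The class II genes H2-Eb1 (3.15), H2-Aa (2.73), H2-Ab1 (1.96) and Cd74 (2.13) and the class I light chain B2m (0.86) passed when adjusted over the list alone, 5 of 16, and 0 of 16 over all genes tested. The list mean differed by 0.96 (SE 0.47, exact permutation p = 0.0714, n = 6 each), and by 1.32 (SE 0.64) with the column block. Without 1 array the median ran from 0.34 (knockout replicate 6) to 0.91 (intact replicate 1), and the list was called each time. Both lists lost their call with the label series as a block, where the mean differed by 0.11 (SE 0.38) for interferon genes and by 0.03 (SE 0.65) for antigen presentation. In series A the interferon list mean was 0.56 over the 2 intact and 0.67 over the 3 knockout animals, against -0.94 over the 4 intact animals outside it. The mean of microglia and macrophage markers was likewise 0.57 over the 2 intact animals of series A and -0.51 over the other 4.

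**Figure D2:**
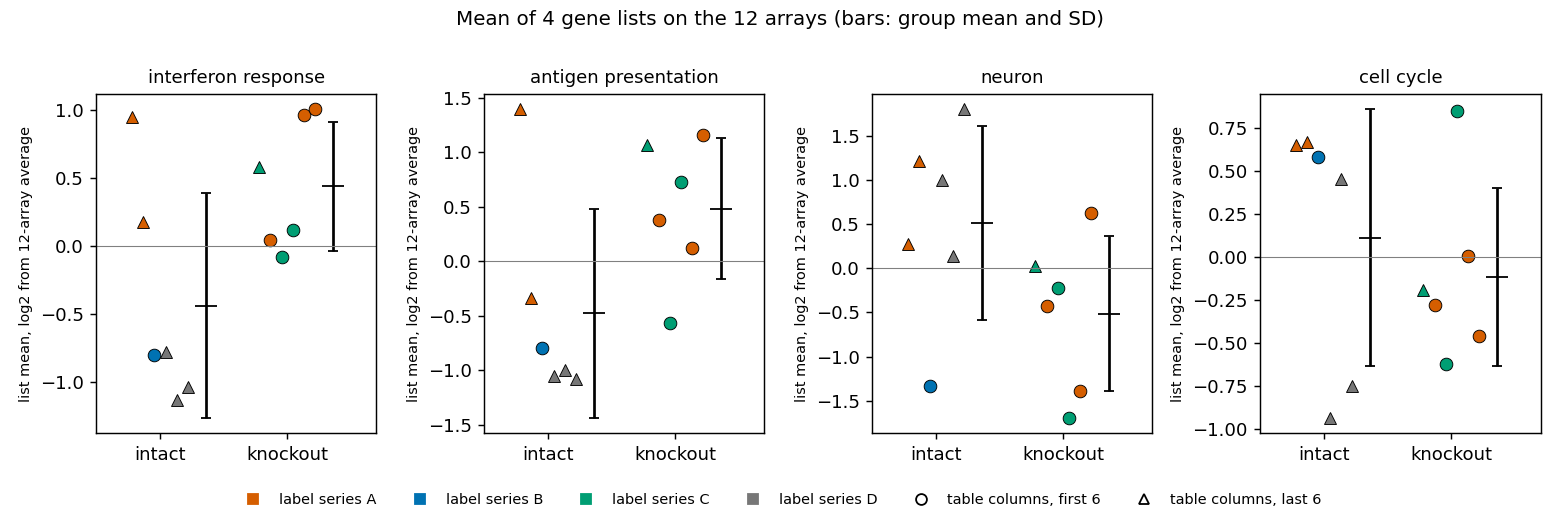
Mean of 4 gene lists (vertical axis, log2 deviation from the average of the 12 arrays) in intact and knockout tumours, 1 point per array, with the mean and SD of each group as a bar at its right, colours for the label series and symbols for the column block. The 4 intact arrays outside series A lie lowest for interferon genes, and neuron markers run from -1.34 to 1.80 in intact and from -1.69 to 0.62 in knockout tumours.

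Neuron markers were lower in knockout tumours as a list. All 15 measured members were below 0, with a median of -1.13, among them the synaptic kinase Camk2a (-1.47), the nuclear marker Rbfox3 (-1.39) and Nrgn (-1.21). Camera gave an adjusted p of 9.82e-05, and the adjusted p was 0.807 with an estimated correlation, and no single member passed over the list alone. Myelin genes had a median of -0.46 with 1 of 15 above 0 (camera adjusted p = 0.0468, and adjusted p = 0.807 with an estimated correlation), among them Mog (-1.14) and Mag (-0.84). The myelin call was lost without any 1 of intact replicates 2, 4 and 6 and knockout replicates 2 to 5, with adjusted p of 0.148, 0.0697, 0.297, 0.0713, 0.114, 0.175 and 0.0903, and the median shrank most without knockout replicate 4, to -0.25. No background correction, cyclic loess and no filter on dim probes also ended the call (camera adjusted p = 0.0538, 0.0558 and 0.0727). The neuron median was -0.12 and the myelin median 0.18 with the column block in the fit, and neither was called. With age as a covariate the neuron call stayed (median -0.92, adjusted p = 0.0331) and the myelin call was lost (median -0.36, adjusted p = 0.317). The label series gave the same calls, and there neurons had a median of -1.05 (adjusted p = 8.79e-05) and myelin one of -0.35 (adjusted p = 0.104). In series A, on which that fit rests, the column block coincides with the group. Its neuron call is therefore no check of a column difference. The neuron list mean was 0.72 higher in knockout within the first 6 columns and differed by -0.86 within the last 6. Astrocyte markers were not called (median -0.48, adjusted p = 0.0603), and the glutamate transporter gene Slc1a2 (-0.93) was the 1 member of 14 that passed over the list alone. The other Slc1a2 probes had smaller differences of the same sign, at -0.37, -0.19 and -0.53. Without 1 array the astrocyte median ran from -0.65 to -0.14, the latter without knockout replicate 4, and the list was called in 4 of the 12 fits. Camera also called the astrocyte list with median scaling and with the mean of a gene's probes (adjusted p = 0.0406 and 0.0227).

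ERK-feedback genes and markers of oligodendrocyte progenitors and proneural glioma were higher in knockout tumours as lists. The first had a median of 0.40 with 9 of 10 members above 0 (camera adjusted p = 0.00974), among them the feedback inhibitor Spry4 (1.03), the transcription factor Etv5 (0.67), Myc (0.62) and Dusp6 (0.41). The second had a median of 0.18 with 17 of 18 above 0 (camera adjusted p = 0.0468), led by Cspg4 (0.71) and Nkx2-2 (0.65). For both the adjusted p was 0.807 with an estimated correlation, and no member passed over the list alone. Both calls were lost with the column block, at medians of 0.06 and 0.04, while with the label series they were 0.38 and 0.38 and both were called. The series fit compares the groups within series A alone, where the column block coincides with the group. It therefore cannot tell a group difference from a column difference. Age as a covariate also ended both calls, at medians of 0.22 (adjusted p = 0.288) and 0.17 (adjusted p = 0.201). The progenitor call was also lost without any 1 of intact replicates 2 and 6 and knockout replicates 2, 3 and 5, with adjusted p of 0.0976, 0.344, 0.0713, 0.114 and 0.0713. Cyclic loess normalization ended that call too (camera adjusted p = 0.0516).

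Of the 28 lists, 6 were called by camera, and 0 with an estimated correlation, by fry or by exact permutation of the list means. Fry, which asks whether a list's genes move on balance in 1 direction and does not set them against other genes, had a smallest adjusted p of 0.622. Without knockout replicate 4 camera called 10 lists. With the column block camera called 7 lists, of which interferon response and antigen presentation were also called without it, and with the label series it called 4. Cell-cycle genes were not called without a block (median -0.18, 5 of 22 members above 0, adjusted p = 0.148), but they were called as lower with array weights (median -0.45, adjusted p = 5.65e-05) and without any 1 of intact replicates 4 and 6 and knockout replicate 4 (medians -0.42, -0.37 and -0.37, adjusted p = 0.000247, 0.00237 and 0.00272), while without intact replicate 1 the median was -0.081. Calls as lower came also with the column block (median -0.45, adjusted p = 0.010) and with the label series (median -0.97, adjusted p = 2.51e-09), and the list mean then differed by -0.45 (SE 0.51) and -0.90 (SE 0.53). With an estimated correlation neither blocked call held, with an adjusted p of 0.941 under the column block and 0 lists called under the label series.

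**Figure D3:**
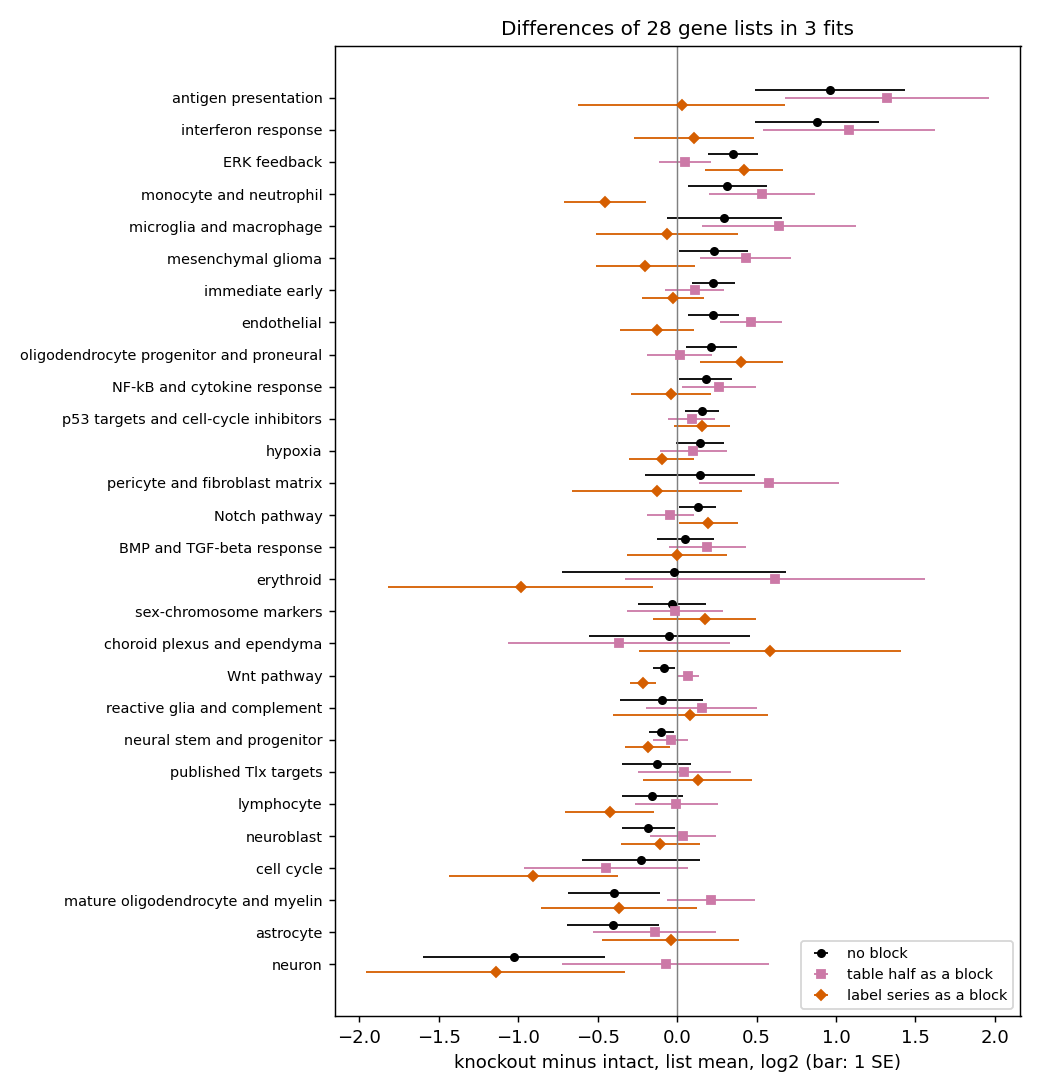
Difference of the list mean, knockout minus intact in log2 units (horizontal axis), for the 28 lists (vertical axis) without a block, with the column block (squares) and with the label series (diamonds), each with a bar of 1 SE. Interferon response lies at 0.88, 1.08 and 0.11 in these 3 fits and neuron markers at -1.03, -0.07 and -1.14.

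Lists tied to Tlx itself were not called. Neural stem and progenitor genes had a median of -0.17 (7 of 16 above 0, adjusted p = 0.412), with Egfr at -0.58 and Hes1 at 0.76, and 1 of 4 further Egfr probes had the opposite sign. Of the published Tlx targets, 6 of 10 were measured, with a median of -0.13 (adjusted p = 0.987). Cdkn1a, a cell-cycle inhibitor that Tlx is known to repress, was at -0.35, Gfap at -0.73, Aqp4 at -0.47, S100b at 0.49, Sirt1 at 0.09 and Pax2 at 0.19. None of the 6 passed over the list alone, and these values depended on single arrays: Gfap was at -0.22 and Aqp4 at -0.035 without knockout replicate 4, Cdkn1a at -0.082 and Sirt1 at 0.19 and the list median at 0.054 without intact replicate 4, and Pax2 at 0.30 without knockout replicate 1.

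The remaining lists were not called either in the fit without a block. Medians were 0.05 for p53 targets, 0.08 for the Notch, 0.03 for the Wnt and -0.05 for the BMP and TGF-beta lists, 0.15 for hypoxia, 0.12 for NF-kB and cytokine response, -0.08 for reactive glia and 0.14 for mesenchymal glioma genes. Among cell types, the median was -0.04 for neuroblasts, 0.16 for microglia and macrophages, 0.27 for monocytes and neutrophils, -0.21 for lymphocytes, 0.25 for endothelium, 0.35 for pericytes and fibroblast matrix, -0.04 for choroid plexus and ependyma and -0.04 for erythroid cells. Immediate early genes had a median of 0.16. The adjusted p of these lists lay between 0.0603 and 0.987. Many of the medians depended on single arrays. Without 1 array they ran from 0.017 to 0.17 for p53 targets, -0.026 to 0.20 for Notch and -0.084 to 0.24 for hypoxia. The same ranges were 0.025 to 0.35 for microglia and macrophages and 0.14 to 0.61 for pericytes and fibroblast matrix. Endothelial, microglia and macrophage, and mesenchymal glioma genes were called as higher with the column block (medians 0.39, 0.42 and 0.29, adjusted p = 9.80e-05, 0.0301 and 0.00825) and with age as a covariate (medians 0.16, 0.45 and 0.44, adjusted p = 0.0373, 0.0378 and 0.000737), and pericyte genes with the column block alone of these fits (median 0.77, adjusted p = 0.010). Leaving out 1 array, the endothelial list was called in 4 of 12 fits, mesenchymal glioma in 3, microglia in 2 and pericytes and p53 targets in 1 each, and the mean of a gene's probes also gave an endothelial call (adjusted p = 0.0320). None of the first 4 was called with the label series or, under the column block, with an estimated correlation. For 6 of the 28 lists, the published Tlx targets, Wnt, BMP, neuroblast, erythroid and sex-chromosome lists, the test, the median and the mean did not share a sign.

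Within the microglia and macrophage list, members passed in both directions over the list alone. P2ry12, a receptor of resting microglia, was at -2.13 and the integrin gene Itgam at -0.61, while the Fc receptor chain gene Fcer1g was at 4.10, and 0 of 16 passed over all genes. P2ry12 read 10.1 ± 0.21 in intact and 7.95 ± 1.59 in knockout tumours (SD, n = 6 each). With the label series, P2ry12 was at -1.94 and Fcer1g at -0.07. Rgs5 (-1.56) and Kcnj8 (-0.78), both markers of pericytes, passed as lower over their list alone, 2 of 14, although 11 of the 14 members were above 0, and 0 of 14 passed over all genes.

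Sex markers served as a quality check. Xist read 8.89 to 9.44 on intact replicates 1 and 4 and knockout replicate 2 and at most 4.72 on the other 9 arrays, and the Y-linked Eif2s3y read at most 4.78 on those 3 arrays and at least 7.56 on the others, so both groups hold both sexes. Xist was at -0.81 between groups, Eif2s3y at 0.35, Kdm5d at 0.36 and Uty at -0.03, and none passed (list adjusted p = 0.987). These values depended on single arrays. Without 1 array Xist ran from -1.66 to -0.18, Eif2s3y from -0.33 to 1.14 and Kdm5d from 0.022 to 0.80.

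**Figure D4:**
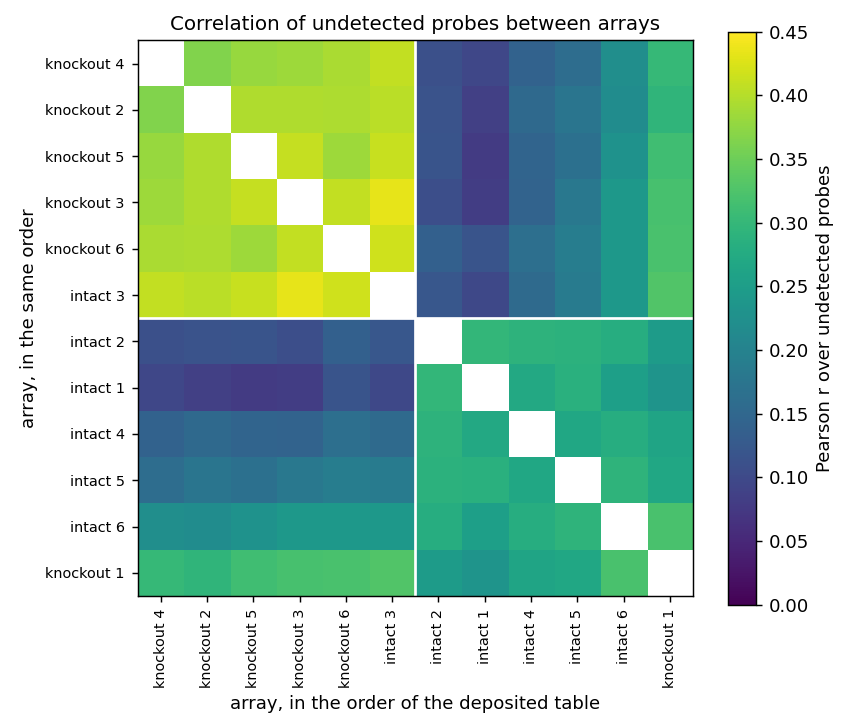
Pearson r between arrays over the 9153 probes detected on no array, with arrays in the order of the deposited table on both axes and white lines between the first and last 6 columns. The median r was 0.40 within the first 6 columns, 0.28 within the last 6 and 0.16 between them.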

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

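All tests of explanations in this part were chosen after the result was seen, except the count of other divisions of the arrays. Of 232 sets of 6 values examined, 17 held 1 array far from the other 5, where chance alone gives about 11.6.

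Among genes, Samd9l read 11.25 on knockout replicate 5, against 10.26 to 10.52 on the other knockout arrays. Parp10 read 4.57 on intact replicate 1, against 4.33 to 4.41. Gnat1 read 7.37 on knockout replicate 1, against 4.07 to 4.99. Rnf43 read 4.70 on knockout replicate 2, against 4.24 to 4.34, and Sirt1 read 8.41 on intact replicate 4, against 7.73 to 7.93. Knockout replicate 2 was also apart in Kdm5d (4.22) and Xist (9.44) and in the mean of the sex-chromosome markers (-0.63).

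Among list means, the published Tlx targets were at 0.58 on intact replicate 4 and at -0.96 on knockout replicate 4. Knockout replicate 4 was also apart in hypoxia genes (0.74), NF-kB and cytokine genes (-0.25) and immediate early genes (0.70). The ERK-feedback mean was 0.24 on intact replicate 3, and the mesenchymal glioma mean was 0.71 on knockout replicate 1. On intact replicate 1 the antigen-presentation mean was 1.39, against -1.08 to -0.34 on the other intact arrays, and the lymphocyte mean was 0.83, against -0.33 to 0.06.

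Interferon-response genes were higher in knockout tumours by 0.88 in the list mean (SE 0.39). A larger share of microglia and macrophages stays undecided. The interferon mean less the microglia mean differed by 0.58 (SE 0.23, exact two-sided permutation p = 0.0390, n = 6 each) but by 0.17 (SE 0.38) with the label series, and the markers moved in both directions, so their mean is a poor measure of the share. The column block left a difference of 1.08 (SE 0.54) and age one of 0.76 (SE 0.63), both too imprecise to decide. With the label series the difference was 0.11 (SE 0.38). That fit rests on 2 intact and 3 knockout arrays and is also too imprecise to decide, since it does not exclude 0.88. A candidate explanation, which stays open, is that the 4 intact animals outside series A were low in these genes for a reason tied to the series. Loss of Tlx and the older age of the knockout animals stay open as well.

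Without intact replicate 1 the fit called 88 genes higher and 15 lower. Low signal over background is argued against, since 52.0% of probes were detected on that array, against 50.8% to 54.8% on the others. On the genes called without it, the array lay at 0.917 on a scale from the other intact arrays (0) to the knockout arrays (1), as a mislabelled knockout might, but its Lyzl4 probe read 7.58, against at most 4.70 on any knockout array. Adgrf5 (5.36), Sec22c (6.88) and Erdr1 (10.7), which were also called without it, lay outside the knockout ranges of at least 5.77, at least 7.33 and at most 10.2. These genes were named for their difference in the fit that counts this array as intact, where their groups were fully separated. Its place outside their knockout ranges was thus largely fixed by that choice. Sec22c is also only 2 measured genes from Lyzl4 on chromosome 9. The animal was collected at 42 days, against 48 days or more for knockout animals. The Lyzl4 value and the age go with its label, but they are 1 gene and 1 age. Most of the genes called without it go the other way, which their choice favours, so a mislabel stays undecided. On the genes called without the pair, both intact arrays of series A lay towards the knockout arrays, the lower of them at 0.897. With all arrays only 2 genes were called, so that position largely followed from how the genes were chosen. It cannot tell a difference between series of animals from errors in single arrays.

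Lyzl4 was at least 6.79-fold lower in knockout tumours, none of which detected it. A difference between the column blocks as its whole cause is argued against, since the adjusted p was 0.000719 with the block, within a range of 1.67e-06 to 0.525 over the alternatives. The groups also differ in the Cre transgene, and a chromosome segment inherited with it could carry a variant of Lyzl4 or of its probe site. Of the 20 nearest measured neighbours on chromosome 9, 4 had p below 0.01, or 20% against 3.60% of other genes (Fisher's exact p = 0.00522), but 1 of 20 with the column block (exact p = 0.310). Of those 4, Sec22c (0.92, with the block 0.95) and Nktr (-1.25, with the block -1.34) kept their size. Klhl40 (0.84, with the block 0.39) and Hhatl (-1.59, with the block -1.04) shrank. The lower count thus partly reflects a less precise fit. The segment and an effect of Tlx cannot be told apart here, because Cre and knockout coincide in every animal.

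Chance is not excluded for the counts of genes and lists. Of 100 divisions of the 12 arrays into equal groups, the real one included, 6 called at least 1 gene in their larger direction, as the real one did in each direction, and the highest other called 23. As many as 6 lists were called in 66 of the 100, and the highest other called 16. The real division gave 1690 genes at an unadjusted p below 0.05, and 5 of the 100 gave as many, with 2085 in the highest. Other divisions called up to 24 genes in both directions together, and whether a structure among the samples gave these calls was not tested. The division along the columns called 0 genes by limma and 6 lists, with 2019 genes at an unadjusted p below 0.05. With the column block, the real comparison called 0 genes as higher and 1 as lower, and 608 and 477 at an unadjusted p below 0.05.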

How the results depend on the processing

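The column block, the label series, the fits on 1 column block alone, the fit without the 5 arrays lacking the Pdia3 probe, and the permutation of list means were tests chosen after the data were seen. No paired analysis was possible because the groups share no replicate number from the labels. The difference in age kept its direction and call in the medians (17.5 days) and without each animal (13.97 to 20.17 days). Nr2e1 was lower and uncalled throughout. A slide block could not be fitted, since no slide is recorded.

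The count of higher genes was 0 without background correction, in the authors' value table, with the mean of a gene's probes, with array weights, with age as a covariate, with the column block, with the label series and in the last 6 columns alone. It was 2 with no filter on dim probes and 53 in the first 6 columns alone. The count of lower genes was 3 in the first 6 columns, 0 in the last 6 and 2 when each probe was tested on its own. Beside those limma counts of 0, 347 genes were higher and 379 lower at an unadjusted p below 0.05 in the last 6 columns, and 325 and 274 with the label series. Without 1 array each, higher genes numbered 0 to 88, lower genes 1 to 15 and called lists 4 to 10, with the extremes of 88 and 15 without intact replicate 1, of 4 lists without knockout replicate 5 and of 10 without knockout replicate 4. Lists called numbered 0 with an estimated correlation, with fry and by exact permutation. Without the 5 arrays lacking the Pdia3 probe, camera called the neuron, interferon and antigen-presentation lists, among others (adjusted p = 0.00806, 2.02e-08 and 5.59e-10). Of the knockout arrays, that fit keeps replicates 1 and 6 alone.

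For some lists the direction of the test reversed, not always with the sign of the median. In the fit with the column block the progenitor list kept a median of 0.041 while its test turned downward, and the myelin median became 0.18. In the first 6 columns alone the medians were -0.067 for ERK feedback, -0.13 for progenitors, -0.021 for myelin and 0.94 for neurons, and in the last 6 they were 0.71 for reactive glia and 0.28 for myelin. Without the 5 arrays lacking the Pdia3 probe they were 0.058 for myelin and -1.11 for erythroid cells. The main medians of myelin (-0.46) and erythroid cells (-0.041) were both below 0, so the myelin median in the first 6 columns and the erythroid median kept their sign. The column-block fits rest on 1 array of a group in each block, and the cause of these reversals was not tested. Over the named genes and the alternatives other than leaving out 1 array, calls were lost 11 times and gained 2 times, an uncalled difference changed sign 55 times, and direction and side held 1204 times. Under median scaling 621 genes were higher and 986 lower at an unadjusted p below 0.05, against 881 and 809. Lyzl4 has no value in the first 6 columns alone, where its probe did not pass the detection filter.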

Other observations

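The tests in this part, other than the test of single probes, were chosen after the data were seen, and the genes and arrays singled out were chosen after their values were seen.

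Intact tumours were not alike in immune genes and in some others. Fcer1g, the signalling chain of Fc receptors on myeloid cells, read 11.3 to 12.2 on the 2 intact arrays of series A and 4.22 to 6.20 on the other 4, while knockout tumours read 10.4 to 12.2. The class II genes followed the same division, with H2-Eb1 at 8.04 to 10.2 on the series A intact arrays, 4.38 to 4.78 on the other intact arrays and 7.80 to 10.3 on knockout arrays. Cd74 read 9.17 to 11.6, 7.47 to 8.53 and 9.41 to 11.9 in the same order, and Ifit3 10.3 to 10.9, 7.90 to 8.95 and 10.3 to 12.2. The division was not confined to immune genes. In the same order Trim62 read 8.13 to 8.17, 6.09 to 6.54 and 8.47 to 9.54. A probe of Cfl1 read 8.22 to 8.32, 4.09 to 4.35 and 7.71 to 9.49. The cause of the division was not tested.

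Lyzl4 did not follow that division, and Erdr1 followed it in part. Lyzl4 was at 7.06 to 7.58 on the intact and 4.31 to 4.52 on the knockout arrays of series A, and Erdr1 at 10.7 on both intact and 6.36 to 10.2 on the 3 knockout arrays of series A, with 11.4 to 13.2 on the other intact arrays, and its difference shrank from -3.46 to -2.10 (SE 1.04, adjusted p = 0.999) with the label series. Itga9, also on chromosome 9 and 25 measured genes from Lyzl4, had 1 probe called when each probe was tested on its own, with a difference of -1.66 (SE 0.23, limma adjusted p = 0.0393), while its other probes were at -0.10 and -0.44.

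The number of genes called depended on the intact animals of series A. When both intact arrays of series A were left out, limma called 343 genes, 257 higher and 86 lower. Leaving out any other of the 15 pairs of intact arrays gave 1 to 7 genes, with a median of 1. On the 343 genes the series A intact arrays lay at 0.990 and 0.897 between the other intact arrays (0) and the knockout arrays (1). These genes were chosen without the pair, but all arrays together gave only 2 calls. The position therefore largely restates the rise in calls and is no separate evidence. With the series as a block, which rests on 2 intact and 3 knockout arrays, only Lyzl4 was called. What the numbers stand for is not given in the labels, so the 343 genes are not reported as an effect of Tlx.

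Each array was also placed between the groups on 100 genes picked without it. The 6 knockout arrays were nearer their own group, at 0.53 to 1.04, but knockout replicates 1 (0.53) and 6 (0.57) lay close to midway (0.5). The fit without intact replicate 1 called 103 genes. The fits without each other array called 1 to 5, so most of their 100 genes were uncalled. Of the intact arrays, replicates 4, 5 and 6 lay at -0.01, -0.04 and -0.14, and replicates 1, 2 and 3 at 0.92, 0.83 and 0.65, nearer the knockout group. Knockout replicate 1 and intact replicate 3 are also the arrays that stand in the column block of the other group.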
